A study of Mus musculus with 6 samples.

How the data were processed

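RNA was profiled on Affymetrix Mouse Genome 430 2.0 arrays, which measure transcripts with probe sets of short oligonucleotides placed mostly near the 3' end. The 6 arrays held 3 control samples and 3 samples from POMCDicerKO mice, in which the microRNA-processing enzyme Dicer was deleted in cells that express Pomc. Per the labels, the tissue was microdissected arcuate hypothalamus of mice aged 2 weeks, on a mixed background of C57Bl/6J, FVB/N and 129, and the samples were independent. Groups and replicate numbers were taken from the sample titles. Whether each sample held 1 animal or a pool is not given in the sources used here.

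The deposited values were log2 expression values, 1 per probe set and array. Per the submitters' processing notes they were made with RMA and the affy package, whose versions are not given in the sources used here. RMA corrects the background, normalises the arrays by quantiles and summarises the probes of each set, so a difference shared by most transcripts of an array would have been removed before deposit. The values were used as deposited, and no unused sample column was present (0). Array medians lay between 6.02 and 6.05, and the number of arrays, not a read depth, limits the precision. Probe sets near the lower end of the scale, which began at 3.05, carry little signal over background, and their differences are compressed.

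Of the non-control probe sets, 45037 were tested and 64 AFFX control probe sets were left out. The probe gene table gave 1 gene symbol to 34945 probe sets and several to 932. It did not list the other 9160, which are unnamed here. Symbols were updated through Entrez identifiers in the RefSeq gene table of assembly GRCm38.p6, where 34741 of the single symbols were found. That table served only for names, chromosomes and the order of genes, since the value table names no genome build, and no coordinates are printed. For gene lists, each of 18193 genes was represented by its probe set with the highest mean over all 6 arrays.

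POMCDicerKO was compared with control by limma 3.58.1 (lmFit and eBayes without trend or robust options) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Fold changes are POMCDicerKO minus control on the log2 scale, errors of fold changes are limma's standard errors, and intervals are 95% intervals. Single values were compared by a two-sided exact permutation test, which with 3 against 3 samples cannot go below p = 0.1. The 41 gene lists, their members and the rule for naming genes were fixed before the data were examined. Lists of at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with limma's fry, each adjusted over the 41 lists. The 100 genes nearest to Dicer1 in gene order, 50 on each side, formed a further set, because a mixed background can leave DNA of another strain beside a targeted gene.

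The naming rule took Dicer1 and Pomc always. It took up to 10 genes in each direction past the threshold with no overlap between the groups. Where fewer passed, it filled up to 10 with the smallest unadjusted p among probe sets with an unadjusted p under 0.01, no overlap and a mean of at least 6. It also took up to 4 members of each list with the smallest unadjusted p, and any member past the threshold adjusted over the list alone. Lists without a call are described with fewer members, mostly 1 or 2.

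The scripts were tested on simulated data before use. With all 45037 probe sets and 200 of them changed, 53% were recovered at a true log2 change of 0.5, 98.5% at 1 and 99.5% at 2, with 9, 10 and 10 false calls. With the 41 lists, a list shifted by 0.5 was recovered and 0 other lists passed. Noise was drawn independently for each probe set, so the simulation gives no measure of false calls where genes vary together. In the data the estimated correlation was 0.829 for myelin genes and 0.881 for meningeal genes. Simulated noise took limma's moderated variances, and the adjusted threshold depends on how many probe sets change. The recovered shares therefore do not carry over to the data, where 114 probe sets changed at least 1.5-fold and 0 passed.

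Alternatives planned before the data were examined were centring each array on its median, a further quantile normalisation, filters at the median level or at a mean of 6, a trend or robust prior, array weights, 1 probe set per gene, no moderation, a replicate block, a minimum change of 1.5-fold, the mean of all probe sets of a gene for lists, and leaving out each array in turn. After the data were seen, controls 1 and 2 were also left out together, leaving control 3 as the only control, which limma assumes to vary like the POMCDicerKO arrays, and the POMC neuron list was tested without Pomc and without Anxa2 and Glipr1. The labels give no hybridisation or scan batch, so none was tested.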

Results

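The data were log2 expression values of 45037 probe sets on 6 arrays of arcuate hypothalamus from mice aged 2 weeks, 3 from controls and 3 from POMCDicerKO mice. The arcuate nucleus holds the neurons that make pro-opiomelanocortin (Pomc), the precursor of the appetite-suppressing melanocortin peptides. Dicer cuts precursor hairpins into mature microRNAs. The comparison asked how the arcuate transcriptome differed when Dicer was missing from Pomc-expressing cells. Expression profiles were close to each other, with Pearson r across probe sets between 0.995 and 0.997 within groups and between 0.994 and 0.997 across groups, and 0 arrays were duplicates. Genes are not independent replicates in such a correlation. The median residual SD of a probe set was 0.105 on the log2 scale.

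Pomc was lower on every POMCDicerKO array than on any control array. Its main probe set, 1433800_a_at, averaged 10.19 ± 0.60 (SD, n = 3) in controls and 9.50 ± 0.19 (SD, n = 3) in POMCDicerKO, a log2 fold change of -0.69 with a standard error of 0.27, or 1.62-fold. The 95% interval ran from -1.32 to -0.071. The control arrays read 9.94, 10.87 and 9.76, and the POMCDicerKO arrays 9.35, 9.71 and 9.43. A further probe set, 1455858_x_at, gave -0.67 with a standard error of 0.22, although its groups overlapped. Neither passed limma's threshold over all probe sets (adjusted p = 1 for both). The two-sided exact permutation p was 0.1 for the first, the smallest that 3 against 3 can give, and 0.2 for the second. Control 2 held the highest Pomc value, and without it the log2 fold change of 1433800_a_at was -0.35. Without controls 1 and 2, which stood apart in meningeal transcripts, it was -0.26, with control 3 as the only control.

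Dicer1 itself did not differ detectably. Probe set 1460571_at averaged 9.21 ± 0.032 (SD, n = 3) in controls and 9.23 ± 0.082 (SD, n = 3) in POMCDicerKO, a log2 fold change of 0.018, or -0.029 without POMCDicerKO replicate 3. Probe set 1427941_at gave 0.09 with a standard error of 0.096. Their exact permutation p values were 0.8 and 0.6. POMC cells are a small part of the dissected tissue, and a probe set outside the deleted part would not respond, so these values do not check the genotype labels.

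**Figure D1:**
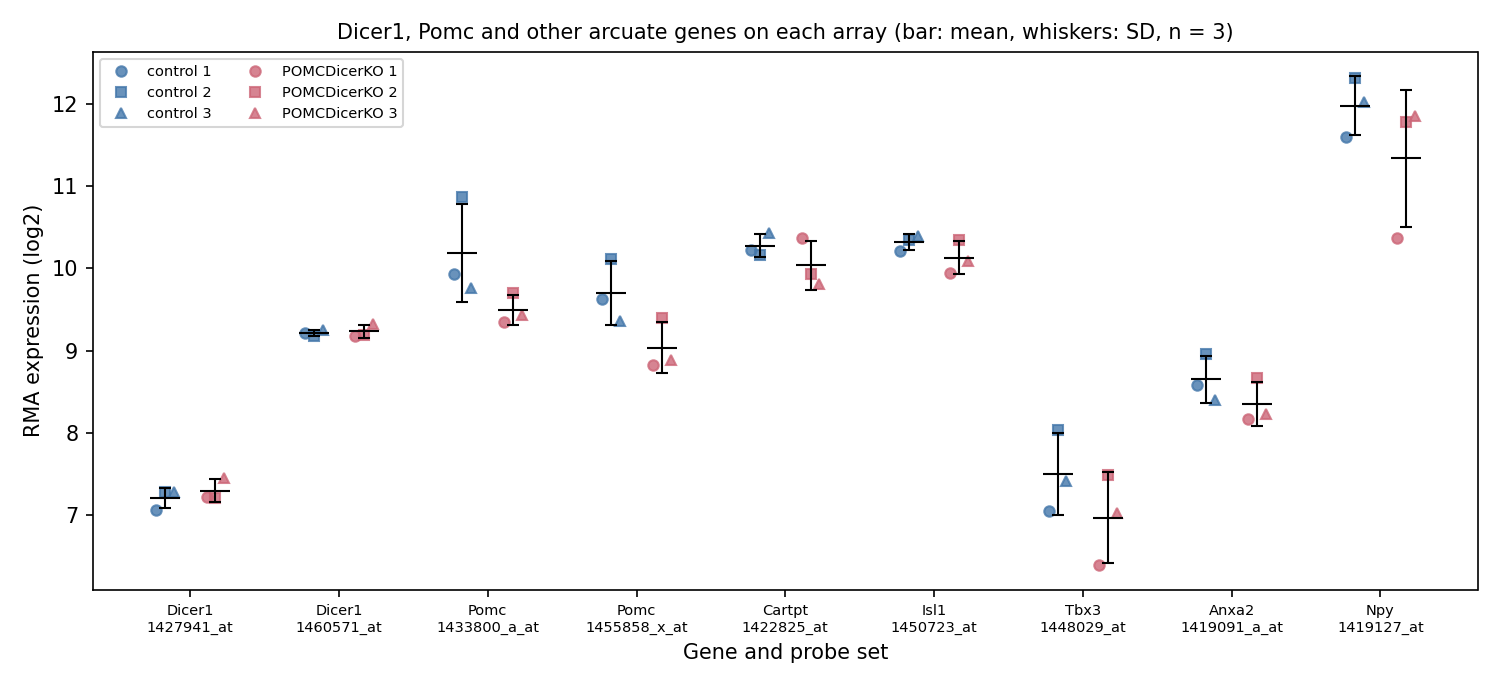
Log2 RMA expression (vertical axis) of Dicer1, Pomc and other arcuate genes, 1 position per probe set, on the control (blue) and POMCDicerKO (red) arrays, with markers for the 3 replicates, bars for the mean and whiskers for the SD. Pomc 1433800_a_at sits at 9.76 to 10.87 in controls and 9.35 to 9.71 in POMCDicerKO, while the Dicer1 values overlap.

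Genes of POMC neurons, with Pomc among them, were lower as a group. Of 13 measured members, 11 were lower, and the median log2 fold change was -0.19. Camera gave an adjusted p of 0.00474, but the adjusted p = 0.644 with an estimated correlation. The estimate was -0.051, and before adjustment over the lists p was 0.0207 by camera with it. By fry, p was 0.0117 before adjustment and 0.461 after it. None of the members passed over all probe sets and 0 passed adjusted over the list alone. Besides Pomc, the members with the smallest p were Isl1 and Tbx3, transcription factors of arcuate neurons, at -0.19 and -0.53, and the calcium-dependent membrane-binding protein Anxa2 at -0.30. Without POMCDicerKO replicate 1 Isl1 was at -0.096 and Tbx3 at -0.24, and without control 2 Anxa2 was at -0.14. The list median was -0.12 without POMCDicerKO replicate 3. Without Pomc, 10 of 12 were lower and the list was past the threshold (adjusted p = 0.0216), as it was without Anxa2 and Glipr1 (adjusted p = 0.0223). It was no longer past without control 1 (adjusted p = 0.0502), without POMCDicerKO replicate 3 (adjusted p = 0.0754) or without controls 1 and 2 (adjusted p = 0.099), and its alternatives ran from 3.63e-05 to 0.644.

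Neighbouring arcuate neurons gave no list past the threshold, but whether their genes differed from those of POMC neurons was not tested. Without Pomc, the POMC neuron list had a median of -0.185. The 6 measured AgRP/NPY genes, from the appetite-promoting neurons, had a median of -0.15 (camera adjusted p = 0.313). Npy averaged 11.98 ± 0.36 (SD, n = 3) in controls and 11.34 ± 0.84 (SD, n = 3) in POMCDicerKO, where array 1 alone read 10.38. Its log2 fold change of -0.64 was -0.16 without that array. Otp, Acvr1c and Npy2r were at -0.10, -0.22 and -0.19, and Npy2r turned to 0.006 without control 2. The list passed without POMCDicerKO replicate 2 (adjusted p = 0.0195). Among 15 other arcuate genes, 12 were lower, with a median of -0.058 (camera adjusted p = 0.2). Slc6a3, the dopamine transporter, was at -0.36 with a standard error of 0.084 and was the only member of that list past the threshold adjusted over the list alone (adjusted p = 0.0408). It lies on chromosome 13, within the stretch where genes with the smallest p clustered, as described in the closing section. Esr1, the oestrogen receptor, and Pdyn, the prodynorphin precursor, were both at -0.22, and Esr1 was at -0.003 without control 2. With control 3 as the only control the list passed (adjusted p = 0.00449; alternatives 0.00449 to 0.908). Genes of peptide processing (adjusted p = 0.788) and of melanocortin, leptin and insulin signalling (adjusted p = 0.964) had medians of -0.019 and -0.026. Chga, a granin of secretory granules, was at -0.15.

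Genes of microRNA production had a median of -0.02 over 14 measured members, 6 higher and 8 lower (adjusted p = 0.964). Tnrc6b, of the silencing complex, was at 0.083, the Argonaute protein Ago2 at -0.11, the Dicer partner Tarbp2 at -0.10 and the precursor exporter Xpo5 at -0.088. The 8 microRNA host transcripts, 4 higher and 4 lower, had a median of -0.034 (adjusted p = 0.796), with Mir99ahg at -0.20 and Mir9-3hg at -0.089. Mature microRNAs were not analysed here.

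Across all probe sets, 0 passed limma's adjusted threshold. The smallest adjusted p was 0.417, and 0 passed without moderation. At an unadjusted p under 0.05 there were 1098 probe sets, 557 higher and 541 lower, where chance alone would give 2252. The groups did not overlap at 2865 probe sets (6.36%), against 10% by chance. With a robust, trended prior 1 probe set passed, Rps9 1434624_x_at (adjusted p = 0.0362). Leaving out control 1 brought 1 past, for the kainate receptor gene Grik1, and leaving out control 3 brought 2 past, for Ogn and Slc6a20a, named after their values were seen. The unadjusted count was 2075 without control 1 and 1868 without controls 1 and 2.

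The genes with the smallest p and separate groups are described by value, since none passed. Ntrk2, the receptor of brain-derived neurotrophic factor, gave -0.64 with a standard error of 0.069 at 1435305_at (adjusted p = 0.417), with 10.21 ± 0.054 in controls and 9.57 ± 0.072 in POMCDicerKO (SD, n = 3 each). Its other probe sets disagreed in size and partly in sign, from -0.55 at 1446712_at to 0.22 at 1420837_at. The ribosomal protein gene Rps9 gave -0.67 at 1434624_x_at (adjusted p = 0.417), but -0.005 at 1433689_s_at, of either sign with single arrays left out (0.029 without control 2 and 0.032 without POMCDicerKO replicate 1), and 0.14 at 1426958_at. Below control levels were also Erdr1 (-0.41), G530011O06Rik (-0.47), Nhlrc1, a ubiquitin ligase (-0.33), Erc1 of the presynaptic active zone (-0.71), the fatty acid transporter Cd36 (-0.38), the lysosomal enzyme Naglu (-0.30), Slc6a3 and Tut4, a uridylyltransferase that acts on let-7 precursors (-0.37). Above control levels were the zinc finger gene Zfp874a (1.04), Anln, an actin-binding protein of cytokinesis (0.67), the sulphatase Arsk (0.67), the mitochondrial Sdha (0.58), the endothelial receptor Adgrl4 (0.39), Sc5d of cholesterol synthesis (0.34), Gm10037 (0.32), Zfhx3 (0.32), the splicing factor Rbm5 (0.30) and Zmynd8 (0.29). Each had an adjusted p of 1. Of these 20 genes, 7 lie on chromosome 13, 4 higher (Arsk, Zfp874a, Gm10037 and Sdha) and 3 lower (Ntrk2, Nhlrc1 and Slc6a3). Of 29 other probe sets of the same genes with a mean of at least 6, 25 had the same sign and 6 of those an unadjusted p under 0.05. Those of the other sign were Sc5d 1434520_at (-0.59), Rbm5 1452186_at (-0.027) and 1452187_at (-0.062), and Zfhx3 1420650_at (-0.029). Sdha 1426688_at gave 0.092. Probe sets of 1 gene were read on the same 6 arrays, so a shared sign is not separate evidence of a difference between the groups.

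Myelin genes were higher as a group. All 12 measured members were higher in POMCDicerKO, with a median log2 fold change of 0.41 (camera adjusted p = 1.11e-13), but the adjusted p = 0.644 with an estimated correlation. The myelin proteins Mal and Mobp were at 0.57 and 0.47, and Ermn and Opalin, of mature oligodendrocytes, at 0.61 and 0.59. Of the 12, 8 had an unadjusted p under 0.05, 0 passed over all probe sets and 0 passed adjusted over the list alone. Relative to the control mean, the POMCDicerKO arrays stood at 0.75, 0.11 and 0.38, and the controls at 0.11, -0.11 and 0.001, so that POMCDicerKO array 2 lay with control 1. The median was 0.23 without POMCDicerKO replicate 1, where Ermn and Mobp were at 0.38 and 0.30, and 0.54 without replicate 2. POMCDicerKO array 1 was also the lowest for AgRP/NPY genes (-0.55) and tanycyte genes (-0.42) and the highest for lateral hypothalamus genes (0.55). The list was past the camera threshold without any single array, and its alternatives ran from 2e-21 to 0.908. Precursor genes of the same lineage gave a median of -0.033 over 9 members (adjusted p = 0.964), with Sox10 at 0.14 and Olig1 at 0.11. Without POMCDicerKO replicate 1 Olig1 turned to -0.055 and the precursor list passed as lower (adjusted p = 0.0183), where over all 6 arrays the test pointed higher although 6 of 9 members were lower.

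Meningeal and fibroblast genes were lower as a group. All 11 measured members were lower, with a median of -0.63 (camera adjusted p = 2.92e-10), but the adjusted p = 0.644 with an estimated correlation. The prostaglandin D synthase Ptgds was at -2.64 (6.24-fold), and the matrix proteoglycans Dcn, Ogn and Fmod at -1.33, -1.64 and -1.79. These 4 passed adjusted over the list alone (adjusted p = 0.0468 each) and 0 passed over all probe sets. The difference did not separate the groups: relative to the control mean, controls 1 and 2 stood at 0.45 and 0.48 and control 3 at -0.93, among the POMCDicerKO arrays at -0.67, -0.98 and -1.34. The median was -1.04 without control 3 and -0.41 without control 2. With control 3 as the only control the adjusted p was 0.985, and the alternatives ran from 1.66e-31 to 0.985.

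**Figure D2:**
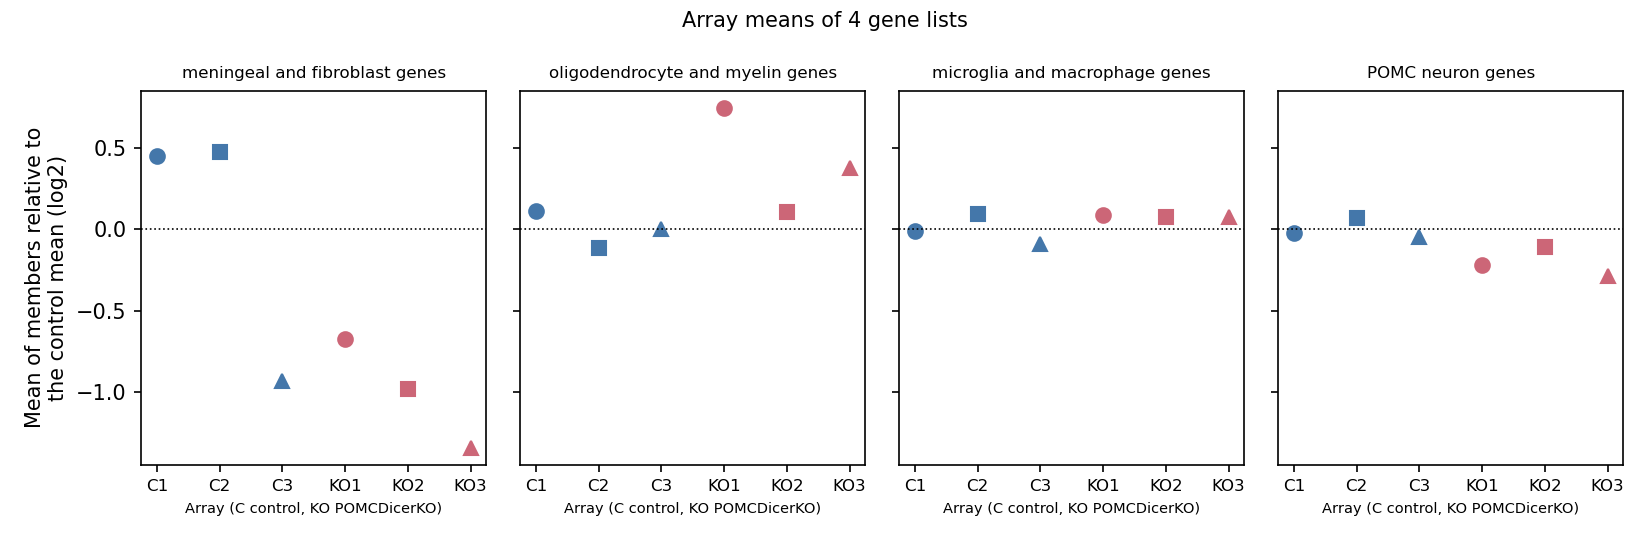
Mean of the members of 4 gene lists on each array, relative to the control mean (vertical axis, log2), for control arrays C1 to C3 and POMCDicerKO arrays KO1 to KO3. Meningeal genes on control 3 (-0.93) lie with the POMCDicerKO arrays, while myelin genes are highest on POMCDicerKO arrays 1 and 3 (0.75 and 0.38).

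Microglia and vessel genes were slightly higher as groups. Of 17 microglia and macrophage genes, 16 were higher, with a median of 0.093 (camera adjusted p = 0.000994), but the adjusted p = 0.644 with an estimated correlation. The Fc receptor Fcgr3 was at 0.16, the adaptor Tyrobp at 0.16, the complement gene C1qc at 0.12 and the protease Ctss at 0.10. Without control 3 the median was 0.029 and the adjusted p 0.177, and the alternatives ran from 1.11e-06 to 0.908. Of 14 endothelial and pericyte genes, 11 were higher, with a median of 0.11 (adjusted p = 0.0248), but the adjusted p = 0.644 with an estimated correlation. Flt1, a receptor of vascular endothelial growth factor, was at 0.19, the tight-junction gene Cldn5 at 0.14 and the pericyte gene Rgs5 at 0.21, while Pdgfrb, also of pericytes, was at -0.28. This list was not past without control 1 (0.0612), control 3 (0.237), POMCDicerKO replicate 1 (0.112) or POMCDicerKO replicate 3 (0.212, with a median of 0.05), or with the mean of all probe sets of a gene (0.0562), and its alternatives ran from 0.00192 to 0.94. In both lists 0 members passed over all probe sets and 0 adjusted over the list alone.

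Cholesterol synthesis and heat shock genes were also higher as groups. Of 13 cholesterol genes, 11 were higher, with a median of 0.049 (camera adjusted p = 0.0216), but the adjusted p = 0.856 with an estimated correlation. Sc5d passed adjusted over the list alone at 1451457_at (0.34, adjusted p = 0.0115), against -0.59 at 1434520_at, and Fdps, Lss and Cyp51 were at 0.15, 0.11 and 0.14. Without POMCDicerKO replicate 1 the direction turned (median -0.04, adjusted p = 0.922), and the list was not past without control 2 (0.133), control 3 (0.0942), POMCDicerKO replicate 2 (0.0789) or controls 1 and 2 (0.147), or with the mean of all probe sets of a gene (0.285). Its alternatives ran from 3.17e-08 to 0.94. All 11 heat shock genes were higher on average, with a median of 0.064 (adjusted p = 0.0406), but the adjusted p = 0.856 with an estimated correlation. The chaperones Hspa1b, Cryab and Dnajb1 were at 0.65, 0.22 and 0.18, but Hspa1b was at 1.30 without POMCDicerKO replicate 3 and 0.16 without replicate 2, and 0 members passed adjusted over the list alone. The POMCDicerKO arrays stood at 0.28, 0.38 and -0.27 relative to the control mean, and with single arrays left out the list was past only without POMCDicerKO replicate 3 (1.36e-10, with a median of 0.23, against 0.005 without replicate 2). It was not past without control 1 (0.0669), 2 (0.107) or 3 (0.115), POMCDicerKO replicate 1 (0.675) or 2 (0.664), controls 1 and 2 (0.408), or with the mean of all probe sets of a gene (0.09). Its alternatives ran from 1.36e-10 to 0.94.

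Blood cell and cell cycle genes were lower as groups. All 7 blood cell genes were at or below control, with a median of -0.15 (camera adjusted p = 0.0216), but the adjusted p = 0.644 with an estimated correlation. That correlation was -0.075, and before adjustment over the lists p was 0.0384 by camera with it and 0.0225 by fry. Alas2, of erythroid haem synthesis, was at -1.22, and Slc4a1, the red cell anion exchanger, at -0.91, while S100a9 and Hba-a1 were both at -0.15. Controls 2 and 3 carried the difference: Alas2 read 6.69, 8.93 and 7.88 in controls and 6.38 to 6.79 in POMCDicerKO, and was at -0.67 without control 2. Relative to the control mean, control 1 stood at -0.28 over the list, among the POMCDicerKO arrays at -0.40, -0.41 and -0.27. The list was not past without control 3 (0.0812) or POMCDicerKO replicate 2 (0.148), and its alternatives ran from 0.00449 to 0.644. Of 15 cell cycle genes, 13 were lower, with a median of -0.064 (adjusted p = 0.0488), but the adjusted p = 0.644 with an estimated correlation. Tyms, Rrm2, Ccnb2 and Bub1 were at -0.17, -0.16, -0.17 and -0.13. The direction turned when only genes with a mean of at least 6 were kept (adjusted p = 0.948). Its median was -0.11 without control 1 and -0.042 without control 2. It was also not past without control 2 (0.43), control 3 (0.0558), POMCDicerKO replicate 1 (0.228) or POMCDicerKO replicate 3 (0.0754), without controls 1 and 2 (0.586), with each array centred (0.0527) or with the mean of all probe sets of a gene (0.0627), and its alternatives ran from 0.0177 to 0.948. In both lists 0 members passed over all probe sets or adjusted over the list alone.

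**Figure D3:**
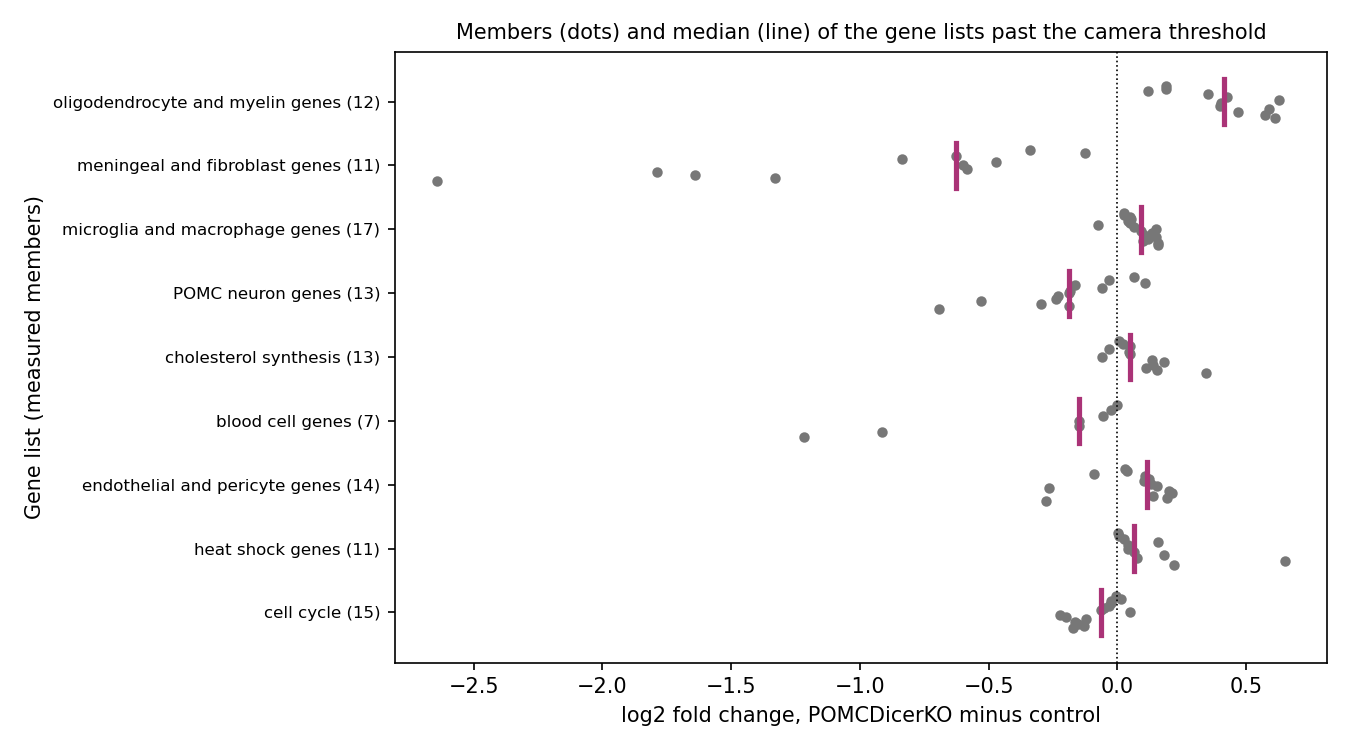
Log2 fold change of POMCDicerKO minus control (horizontal axis) of each measured member (dots) and the median (line) for the 9 gene lists past the camera threshold, with the number of members in brackets. Myelin members all lie above 0 (median 0.41) and meningeal members all below 0 (median -0.63), with Ptgds lowest at -2.64.

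By camera, 9 of the 41 lists passed, 5 higher and 4 lower, against 0 with an estimated correlation and 0 by fry, which tests whether a list moves on balance one way (smallest adjusted p = 0.461). Without control 3 the camera count was 4, and with control 3 as the only control it was 5. Leaving out 1 array moved the median of 8 of the 9 lists by over 1.5 times in at least 1 case, and the values of 90 of the probe sets named or followed here, against 45 that moved less.

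The other 32 lists did not pass, although 12 of them passed under at least 1 alternative, mostly with a single array left out, and 24 turned direction in some alternative. A different array mattered for different lists. Among neighbouring nuclei, ventromedial genes had a median of -0.01 (adjusted p = 0.964) with Fezf1 at 0.065, and paraventricular and supraoptic genes -0.096 (0.755) with oxytocin, Oxt, at -0.37, which was -0.025 without POMCDicerKO replicate 1. Lateral hypothalamus genes had 0.033 (0.92) with the peptide gene Cartpt at -0.24, and suprachiasmatic and clock genes 0.026 (0.244) with prokineticin, Prok2, at 0.15. Pituitary genes had -0.041 (0.788), although Cga, the shared glycoprotein hormone subunit, was at -2.37 and Gh, growth hormone, at 1.64. Tanycyte and ependymal genes had -0.084 (0.244) with Crym at -0.47, and choroid plexus genes -0.088 (0.244), where Kl passed adjusted over the list alone (-0.34, adjusted p = 0.0416). Astrocyte genes had 0.035 (0.461) with S100b at 0.14, and reactive glia genes -0.05 (0.461) with ceruloplasmin, Cp, at -0.39 and the oncostatin M receptor Osmr at 0.26. Neuronal identity genes had 0.03 (0.244) with the neurofilament Nefl and Thy1 at 0.11 and 0.12, and GABA and glutamate transmission genes 0.003 (0.963) with the glutamate receptor subunit Grin2b at 0.25. Neuronal immaturity and progenitor genes had 0.014 (0.889) with Notch1 at -0.15, and neurotrophic and axon guidance genes -0.042 (0.438) with netrin, Ntn1, at -0.25. Tanycyte genes passed without POMCDicerKO replicate 2 (adjusted p = 0.00046), clock genes without control 2 (0.0252) or POMCDicerKO replicate 1 (0.0334), lateral hypothalamus genes without POMCDicerKO replicate 1 (0.0438) and neuronal identity genes without POMCDicerKO replicate 3 (0.0324).

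Among stress and immune lists, p53 and apoptosis genes had a median of 0.015 (camera adjusted p = 0.889), with the pro-apoptotic Bid at -0.36 and Phlda3 at 0.14. Unfolded protein and integrated stress response genes had 0.019 (0.112) with Herpud1 at 0.18, and immediate early genes 0.11 (0.291) with Npas4 at -0.32. Interferon response genes had -0.079 (0.112) with Rsad2 at -0.82, antigen presentation and complement genes -0.001 (0.964) with Psmb9 at -0.11, and cytokine and chemokine genes 0.036 (0.191) with Il1b at 0.15. Oxidative phosphorylation genes had 0.024 (0.244), cytosolic ribosomal protein genes -0.03 (0.319), lipid and glucose metabolism genes 0.009 (0.244) with Pparg at 0.18, and thyroid hormone axis genes 0.11 (0.318) with Nrgn at -0.22. Genes often read as RNA quality or stress had 0.1 (0.244) with Sgk1 at 0.21, which was 0.041 without control 2. Sex-linked genes had -0.013 (0.964). The median and the direction of the test differed in sign for the progenitor, lateral hypothalamus, sex-linked, oligodendrocyte precursor, ventromedial and antigen presentation lists. Immediate early genes passed without control 1 (adjusted p = 0.00156) or POMCDicerKO replicate 3 (0.00185), and RNA quality genes without control 1 (0.0222). Without POMCDicerKO replicate 3, oxidative phosphorylation (0.0324) and unfolded protein genes (0.00805) passed, and without control 3 interferon genes (0.0104).

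The 100 genes nearest to Dicer1 gave no sign of a local difference. Of these, 53 were higher and 47 lower, the median was 0.007, and 0 had an unadjusted p under 0.05, against 2.85% of other genes. Camera gave p = 0.538, and p = 0.641 with an estimated correlation. Without POMCDicerKO replicate 3 the direction turned and camera gave 0.797. Which Dicer1 allele the controls carried is not stated here. If it was the allele of the POMCDicerKO mice, DNA beside it would be alike in both groups, and this set could not show a difference.

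Signs of RNA quality differed little. The 3' minus 5' difference of the Gapdh control probe sets averaged 0.049 in controls and -0.014 in POMCDicerKO, with separate groups (exact permutation p = 0.1), and that of beta-actin 1.24 and 1.16 (exact permutation p = 0.2). None of the 64 AFFX probe sets passed (0).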

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

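Leaving out controls 1 and 2 together, and the lists without Pomc or without Anxa2 and Glipr1, were chosen after the data were seen, as was counting probe sets at an unadjusted p. Without controls 1 and 2, control 3 is the only control and is assumed to vary like the POMCDicerKO arrays. Of 0 probe sets past the threshold, 1 appeared with the robust trended prior (Rps9, adjusted p = 0.0362), 1 without controls 1 and 2, and 0 to 2 when each array was left out in turn, while centring, quantile normalisation, both filters, the trend alone, array weights, 1 probe set per gene, no moderation and the minimum of 1.5-fold gave 0. The count of 1098 at an unadjusted p under 0.05 became 419 and 427 with the filters at the median level and at a mean of 6, and 516 with 1 probe set per gene, all of which test fewer probe sets. It was 1868 without controls 1 and 2, and 874 to 2075 over the single arrays left out. The 9 lists past the threshold became 0 with an estimated correlation, 0 by fry, 5 with the mean of all probe sets of a gene, 5 without controls 1 and 2, and 4 to 10 over the single arrays left out. The cause of these changes was not tested. Dicer1, near 0 throughout, turned to -0.008 with array weights and -0.012 without controls 1 and 2, and ranged from -0.029 to 0.043 over the arrays left out. Pomc kept its direction in every alternative, from -0.91 to -0.26. The set near Dicer1 turned direction by fry (0.917) and its camera value ranged from 0.289 to 0.936 over the arrays left out. The cholesterol list turned without POMCDicerKO replicate 1 (adjusted p = 0.922; range over arrays 3.17e-08 to 0.922), and the cell cycle list with genes of a mean of at least 6 (0.948), where the filter removes dim genes. Over the 9 lists, alternatives left 76 values on the same side, 49 no longer past and 2 turned. The filter at a mean of 6 left too few blood cell genes for a test. Among 133 named probe sets with up to 17 alternatives each, filters removing some, 12 turned. Without controls 1 and 2, Npy2r turned to 0.138, Esr1 to 0.042, Cry1 to -0.049, Sgk1 to 0, Pou3f2 to 0.004, Oxt to 0.267, Ntrk2 1420837_at to -0.163 and Rps9 1433689_s_at to 0.042, the last also to 0.011 by quantile normalisation. Over the arrays left out, Npy2r ranged from -0.379 to 0.006, Otx2 from -0.271 to 0.002, Pcsk1 from -0.301 to 0.017, Kdm5d from -0.176 to 0.017, Olig1 from -0.055 to 0.194 and Rps9 1433689_s_at from -0.034 to 0.032. Ogn passed without control 3 (adjusted p = 0.0141). Signal over background limits the dim probe sets, among them most cell cycle and blood cell genes.

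Of the 32 lists that did not pass, 24 turned direction in some alternative and 12 passed in some, and the adjusted p values that follow come from limma. Unfolded protein genes passed with a mean of at least 6 (0.0232). Over the arrays left out the values ranged for tanycyte genes from 0.00046 to 0.792, oxidative phosphorylation 0.0324 to 0.792, RNA quality 0.0222 to 0.595, neuronal identity 0.0324 to 0.845, immediate early genes 0.00156 to 0.966, AgRP/NPY neurons 0.0195 to 0.709, thyroid hormone axis 0.063 to 0.909, ribosomal proteins 0.1 to 0.916, axon guidance 0.224 to 0.971, paraventricular genes 0.103 to 0.885, pituitary 0.0754 to 0.991, microRNA hosts 0.445 to 0.991, progenitors 0.286 to 0.971, p53 0.334 to 0.991, lateral hypothalamus 0.0438 to 0.991, GABA and glutamate 0.736 to 0.875, melanocortin and leptin signalling 0.369 to 0.792, microRNA biogenesis 0.599 to 0.971, antigen presentation 0.396 to 0.93, ventromedial 0.66 to 0.984, sex-linked 0.602 to 0.986 and oligodendrocyte precursors 0.0183 to 0.841. Without controls 1 and 2 the direction turned for tanycyte (0.953), reactive glia (0.672), astrocyte (0.985), paraventricular (0.548), pituitary (0.672), progenitor (0.821), p53 (0.548), ventromedial (0.672) and sex-linked genes (0.551). With a mean of at least 6 it turned for pituitary (0.963), progenitor (0.948), melanocortin and leptin signalling (0.752) and microRNA biogenesis genes (0.851). By fry it turned for GABA and glutamate (0.944), antigen presentation (0.944), ventromedial (0.942), sex-linked (0.94) and oligodendrocyte precursor genes (0.944). With the mean of all probe sets it turned for microRNA biogenesis (0.536), ventromedial (0.976), sex-linked (0.971) and oligodendrocyte precursor genes (0.976), and by quantile normalisation for microRNA biogenesis (0.946) and antigen presentation (0.994).

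The labels do not say that shared replicate numbers pair the samples, so the main fit held no block. Deviations from the group means of same-numbered samples correlated weakly, at 0.128, 0.0787 and 0.12, which leaves a pairing open. Every sample still correlated best with its own number (highest with another number -0.0177), a hint from the data and not the design. Deviations within a group sum to 0, so the negative values with other numbers largely follow from the positive ones and add no separate hint. With the replicate block 0 probe sets passed, 1396 had an unadjusted p under 0.05 and 11 lists passed, among them tanycyte (0.0143) and interferon response genes (0.0389), and the ventromedial list turned direction (adjusted p = 0.912). Pomc stayed at -0.69 (adjusted p = 1), with an unadjusted limma p of 0.00479 against 0.0334 without the block. The POMC neuron list had a camera adjusted p of 3.63e-05 with the block, against 0.00474 without it. If the numbers do pair the samples, leaving out 1 array also breaks a pair.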

Other observations

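The tests of the splits by probe sets, of clustering on chromosomes, of probe variants, of segregating strain DNA, of genotype in every array for the meningeal genes, of the arcuate share and of pituitary tissue were chosen only after the results were seen. So were the genes of the next paragraph.

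Hormone transcripts of the pituitary varied between single arrays. Gh, growth hormone, read 9.10 and 7.67 on POMCDicerKO arrays 1 and 3 (1456595_x_at), against 4.71 on POMCDicerKO array 2 and 4.24 to 4.61 in controls. Cga read 9.46, 9.87 and 7.80 in controls and 8.68, 5.08 and 6.27 in POMCDicerKO. Prolactin, Prl, lay near the lower end of the scale, between 4.06 and 4.65. Ttr, a thyroid hormone carrier abundant in choroid plexus, read 7.20 on POMCDicerKO array 3 (1454608_x_at), against 9.10 to 11.41 on the other arrays. Pmch, of lateral hypothalamic neurons, read 10.91 on control 2 and 11.28 on POMCDicerKO array 2, against 12.32 to 13.22 elsewhere. Hcrt, also of the lateral hypothalamus, was highest on POMCDicerKO array 1 at 10.72. Xist read 4.51 to 5.52 and the Y-linked Eif2s3y 9.04 to 9.53 over all 6 arrays. The Y-linked Kdm5d and Uty read 7.48 to 7.87 and 6.98 to 7.32. Every array thus held male RNA, and none of these sex-linked genes separated the groups.

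The 10 splits of the 6 arrays are too few for a share under 0.05. The real split had 1098 probe sets at an unadjusted p under 0.05 and the highest other 3632, and all 10 splits had as many as the real one. The other splits ran from 1330 to 3632, on both sides of the 2252 that chance alone would give, while the real count lay below it. Whether the highest split reflects a structure of the samples was not tested. For the 9 lists past the threshold, the highest other split had 11, and 2 of the 10 had as many.

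Genes with the smallest p lay together on chromosome 13. Of 18 named genes with an unadjusted p under 0.001, 9 were on it, where 0.70 would be expected, and 10000 random placements gave 7 at most (share 1e-04, the smallest they can give), which argues against chance placement. They were Bmp6, Nhlrc1, Ntrk2, Ctsl, Zfp458, Zfp874a, Rfesd, Arsk and Slf1, 4 higher and 5 lower, at places 203 to 507 of 705 in gene order. The probe sets of Bmp6, Ctsl, Zfp458, Rfesd and Slf1 were dim, with means from 4.38 to 5.47, under the mean of 6 asked of the named genes. Probe variants alone stay open: 9 of 9 other probe sets with a mean of at least 6, 5 of them for Ntrk2, had the sign of the first, but their median size was 0.238 against 0.642. The dimmer Ntrk2 1420837_at went the other way, at 0.22. Strain DNA segregating in the mixed background is a candidate explanation, since 3 of the 9 other splits also clustered on a chromosome beyond chance, 1 of them with 15 genes on chromosome 9; this count exceeds the real 9, which had been written beforehand as a value against a stretch that differs between the groups, but that bound assumed that no other stretch segregates, so such a stretch stays open too.

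Meningeal and fibroblast genes were lower in POMCDicerKO. A difference between the genotypes stays open. Over the first list control 3 differed from the POMCDicerKO mean by a median of -0.03, and controls 1 and 2 by 1.04, but this rests on 1 array, whose place had been seen. A candidate explanation is more meningeal tissue in the dissections of controls 1 and 2. On a second list of markers, written before its values were seen, 24 of 24 measured genes were lower in control 3 than in controls 1 and 2, with a median of -0.49. The abundant Ptgds read 13.63 and 13.43 in controls 1 and 2 and 10.58 in control 3, though oligodendrocytes of the tissue express it as well.

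Pomc was 1.62-fold lower in POMCDicerKO. Whether a smaller share of arcuate tissue is the whole cause cannot be decided here. Some of the comparison genes, such as Otp and Pdyn, also stand on lists of other nuclei and could fall less with such a share. Over all 6 arrays, 17 genes of other arcuate neurons had a median of -0.12 (SD 0.173), more than 1 SD above the Pomc change of -0.69. That SD is the spread among the genes and not the error of the Pomc change. The 95% interval of Pomc, from -1.32 to -0.071, held -0.12. Npy was at -0.64, but at -0.16 without POMCDicerKO replicate 1. The gap exceeded 1 SD with each of the 6 arrays left out in turn, and was smallest without control 2 (-0.038, SD 0.209, against Pomc at -0.35). Against control 3 alone, a single array, it lay within 1 SD (-0.074, SD 0.293, against -0.26), so a smaller share stays open as part or all of the cause. The bound was revised after these values were seen, to settings with at least 2 arrays per group. The revised bound was met, but a bound that counted the comparison with control 3 alone would not be. Pomc transcript from attached pituitary tissue may contribute and cannot be told apart: Pomc and Cga correlated at r = 0.557 over the 6 arrays (exact permutation p = 0.256; Spearman rho 0.6, exact permutation p = 0.242), and at r = 0.697 without the 2 arrays farthest from the median of Cga. The slope was 0.417 in controls and -0.089 in POMCDicerKO, and 6 arrays are too few to settle it. Growth hormone ran the other way, with r of -0.692 to -0.67 between Pomc and the 4 Gh probe sets (exact permutation p 0.106 to 0.139), and its highest values lay on the 2 arrays with the lowest Pomc. Loss of Pomc expression or of Pomc neurons after deletion of Dicer stays open as the biological explanation and was not tested apart from these.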
